A study of Mus musculus with 6 samples.

How the data were processed

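The series holds 6 disome profiling libraries from livers of male C57BL/6JRj mice, an inbred laboratory strain, kept under cycles of 12 h light and 12 h dark. A disome footprint is the stretch of messenger RNA protected from nuclease by 2 ribosomes stacked against each other. Per the labels' protocols, livers were lysed in buffer with cycloheximide, which halts elongating ribosomes, and lysates of 2 mice were pooled for each library. The pools were digested with 650 U RNase I for 45 min, ribosomes were collected by size exclusion, and libraries were made after ribosomal RNA depletion. Mice were taken at zeitgeber time (ZT, hours after lights on) 0, 2 and 12, with 2 libraries per time point. Each library was taken as a separate pool, so that the spread between the 2 libraries of a time point would cover animals and library preparation together. The titles give both libraries of a time point the same prefix, and the replicate number at their end was used.

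The authors deposited 1 table of RPKM values (reads per kilobase of gene model, scaled by library) per library. Each table lists the same 8941 Ensembl gene identifiers with no header and no symbols. Per the submitters' processing notes, CASAVA 1.82, cutadapt, Bowtie2 2.3.0, STAR, StringTie and edgeR were among the tools, with genome builds GRCm38.p2 and mm10. Their roles, the annotation release, the gene filter and the treatment of reads mapping to several places are not given in the sources used here. Neither monosome footprints nor total RNA were analysed here, so a disome level was not corrected for transcript amount or translation rate.

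The RPKM values were checked for the steps left by whole reads. Within a gene, the values of different libraries were ratios of whole numbers, to a relative tolerance of 5e-13, times 1 constant per library. Whole reads came out directly for 8930 genes (99.88%), and the 11 most abundant genes among the rest were solved through their length. The library constants were 1.00 to 1.01 times the upper quartile of recovered reads per gene, so the deposited RPKM had been scaled to the upper quartile rather than to the total. The recovered gene lengths were multiples of 3 for 95.16% of genes, which marks them as coding lengths. When all 6 reads of a gene share a factor, the recovered reads can be too low. This was corrected in 74 genes through their length. Others may remain too low, since only 73 genes had even reads in every library where chance gives 139.7. The share of whole lengths required in the length step was raised after a lower share had picked a wrong unit of length. Recovered reads totalled 6346387 to 12322651 per library and served for depth, for shares of reads and for 1 alternative test. Intervals and zero limits cover counting error only.

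The main test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 1) of genes with a mean of at least 1 RPKM over the 6 libraries. Of the genes listed, 8355 passed this filter. All 6 libraries entered 1 fit with a mean per time point and no covariate, which left 3 residual degrees of freedom. Variances were moderated with a trend on mean level, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 changes and counts of genes over 2-fold are on the log2(RPKM + 1) scale unless another setting is named. This scale understates the change of low genes. Fold values of single genes are ratios of mean RPKM, or of scaled reads where a floor is given. The same model gave the 3 pairwise comparisons and a moderated F test over the time points. In simulated data for these genes with 200 changed by known folds, the ZT12 against ZT0 test called 0 of 50 genes changed 1.5-fold, 5 of 50 changed 2-fold, 34 of 50 changed 4-fold and 47 of 50 changed 8-fold, among 8355 genes, with 0 false calls.

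The tests, the alternatives, the rule for named genes and 23 functional and 11 cell type gene lists were fixed before the data were examined. The tables do not pair the identifiers with names, and the reference gene table used here carries no Ensembl identifiers (0 of 49997 genes). None of the 8941 identifiers could therefore be matched (0 matched), so no gene symbols are given and the gene lists were not tested. The rule named the genes with the largest rise and the largest fall among those past the threshold whose libraries did not overlap, 10 each way. Where fewer than 5 passed it added the 5 with the smallest p, and it also named clock genes, members of gene lists with calls and the 15 most abundant genes. Because identifiers without symbols carry little meaning, only the first 2 in each direction are printed for each comparison, the other parts of the rule are left out, and the 15 most abundant genes are given by rank. Alternatives were the pseudocount, the filter, the scaling between libraries, the variance prior, the libraries in the fit, the replicate number as a block, the threshold and leaving out each library. Array weights, voom on the recovered reads and the removal of genes listed at 0 in any library were added after the data had been seen. The replicate numbers were not found to pair the libraries across time points.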

Results

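Disome footprints were measured in mouse liver at ZT0, the start of the light phase, at ZT2, and at ZT12, the start of the dark phase, with 2 libraries per time point. The series addresses where ribosomes collide on messenger RNAs in the animal, and the tables summarise this per gene as RPKM. Recovered reads totalled 7197462 and 7816463 at ZT0, 6346387 and 7845062 at ZT2, and 12322651 and 11904184 at ZT12. The median gene held 67 to 144 reads per library. Each library was a pool of 2 livers, and n below counts libraries.

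Disome reads were concentrated on a small set of genes. The gene ranked first had a mean of 66152 RPKM ± 19889 (SD, n = 6), against a median of 7.47 RPKM over all 8941 genes. It had the highest RPKM in 3 of the 6 libraries, and another gene was highest in both ZT0 libraries and in ZT12 replicate 1. The gene ranked 15th still had 8887 RPKM ± 2948 (SD, n = 6). Together the 15 genes with the highest mean held 25.7% ± 1.53 (SD, n = 6) of all recovered reads, and 67 genes held 50%. A mean above 1000 RPKM was found for 126 genes and above 100 RPKM for 1007 genes, while 586 genes lay below 1 RPKM. The share of reads on the 15 genes was lowest in ZT12 replicate 2, at 23.39% (95% exact Clopper-Pearson interval 23.37 to 23.42). It was highest in ZT2 replicate 2, at 27.71% (27.68 to 27.75), and these intervals cover counting error only. None of the 15 genes passed the limma test in any comparison of time points (0 of 15). At an unadjusted p of 0.05, limma counted 5 of them for ZT2 against ZT0, 4 for ZT12 against ZT0 and 6 for ZT12 against ZT2. The gene ranked first had 49393 and 50618 RPKM at ZT0, 97451 and 83925 RPKM at ZT2, and 60888 and 54640 RPKM at ZT12, with a smallest adjusted p of 0.17 in limma.

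The 2 libraries of a time point were closest at ZT0 and farthest apart at ZT2. Across the 8355 tested genes, Pearson's r of log2(RPKM + 1) between replicates was 0.989 at ZT0, 0.948 at ZT2 and 0.976 at ZT12. Genes are not independent replicates, so these values describe the libraries only. The replicates differed by more than 2-fold on this scale for 120 genes at ZT0, 1199 genes at ZT2 and 432 genes at ZT12. The replicate SD fell with the number of reads at every time point. For genes with a mean of 20 to 50 reads it was 0.29 at ZT0, 0.70 at ZT2 and 0.44 at ZT12, and for genes with 2000 reads or more it was 0.17, 0.28 and 0.21. Genes listed at 0 were also unevenly spread, with 4 in each ZT0 library, 97 and 250 at ZT2, and 4 and 52 at ZT12.

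**Figure D1:**
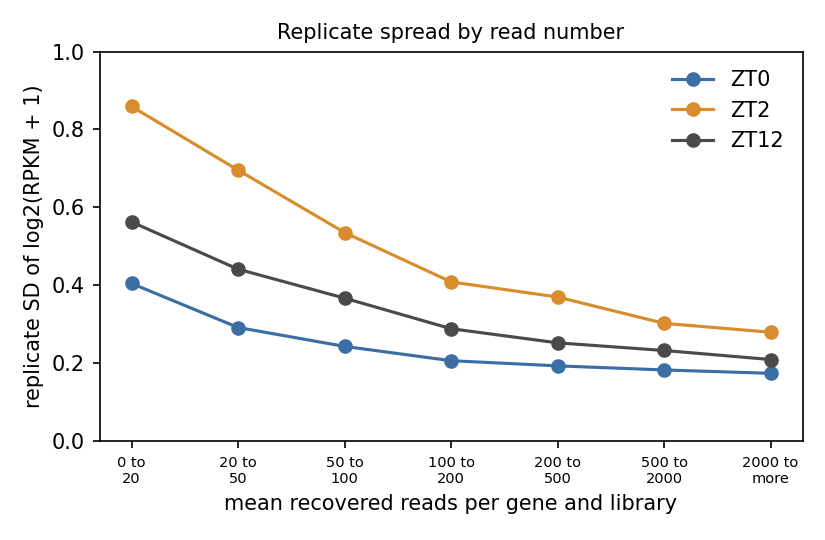
Replicate SD of log2(RPKM + 1) (vertical axis) for genes grouped by their mean recovered reads per library (horizontal axis), 1 line per time point. The ZT2 line lies above the others in every group of genes, at 0.70 against 0.29 for ZT0 in the group of 20 to 50 reads.

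The first comparison asked what changed in the 2 h after lights on. Disome levels of 2 genes passed the test, and both were higher at ZT2. The cell type lists could not be matched, so which cells or tissue these reads came from was not tested. ENSMUSG00000057163 was listed at 0 in both ZT0 libraries and had 170.2 RPKM ± 84.2 (SD, n = 2) at ZT2, from 504 and 1307 recovered reads. Against a floor of 3 reads over the ZT0 libraries together, this was at least 642-fold higher, with a limma adjusted p of 0.0089, and the call was lost in 4 alternatives, at a limma adjusted p of up to 0.114. The 642-fold limit covers counting error only and would be lower if reads came in clumps from few distinct fragments. ENSMUSG00000057163 fell back to 0 and 12 reads at ZT12. ENSMUSG00000023031 had 6.90 RPKM ± 1.96 (SD, n = 2) at ZT0 and 80.2 RPKM ± 19.0 (SD, n = 2) at ZT2. Its log2 change was 3.36 ± 0.29 (SE), with a limma adjusted p of 0.026, and at ZT12 it was at 7.65 RPKM ± 1.49 (SD, n = 2). This call was lost in 6 alternatives, at a limma adjusted p of up to 0.226, among them the fit without the variance trend, the fit on the 4 libraries compared and the fits without either ZT12 library. No gene that was lower at ZT2 passed limma's test (0 genes). At an unadjusted p of 0.05, limma counted 1142 genes, 691 of them lower at ZT2, where 418 in all would be reached by chance. With voom on the recovered reads, chosen after seeing the data, 9 genes were called, 5 higher and 4 lower, and 1 of the 2 genes above was among them. In 50 simulations of unchanged genes with the replicate spread of each time point, the same test called 0.18 genes on average, and 2 of the 50 simulations reached 2 calls. The count moved with the library left out, but a lone library is then assumed to vary like the other groups. ZT2 replicate 2, when left alone, brings 250 genes listed at 0. Such fits cannot show how many genes changed. The log2 change of ENSMUSG00000057163 was 7.85 without ZT2 replicate 1 and 6.80 without ZT2 replicate 2.

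The second comparison set the start of the dark phase against the start of the light phase. Disome levels of 79 genes differed, with 33 higher and 46 lower at ZT12, and 78 of the 79 changed by more than 2-fold. In simulated data this test called 0 of 50 genes changed 1.5-fold and 5 of 50 changed 2-fold, so smaller changes would mostly be missed. The split was 41 higher and 41 lower when every library was scaled to the same total, and 50 and 53 with quantile normalization. The median log2 change was 1.99 among the genes that rose and -1.79 among those that fell. The largest rise was in ENSMUSG00000026475, from 1.09 RPKM ± 1.20 (SD, n = 2) at ZT0 to 115.3 RPKM ± 59.2 (SD, n = 2) at ZT12. Its log2 change was 5.83 ± 0.85 (SE) with a limma adjusted p of 0.029, although its ZT0 value rested on 1 and 9 reads and the call was lost in 7 alternatives, at a limma adjusted p of up to 0.271. With a pseudocount of 5 the log2 change was 4.23, and with 0.1 it was 7.02. ENSMUSG00000022389 rose from 7.11 RPKM ± 3.12 to 110.5 RPKM ± 27.4 (SD, n = 2 each), a log2 change of 3.82 ± 0.49 (SE) with a limma adjusted p of 0.021. This call was lost in 5 alternatives, at a limma adjusted p of up to 0.19, namely without the variance trend and without any one of the ZT0 or ZT12 libraries. The largest fall was in ENSMUSG00000038754, which went from 2627 RPKM ± 7.08 (SD, n = 2) at ZT0 to 69.4 RPKM ± 1.60 (SD, n = 2) at ZT12. This 37.9-fold lower level had the smallest limma adjusted p of the comparison, 2.61e-05, and the libraries at ZT2 lay between, at 1809 RPKM ± 198.4 (SD, n = 2). ENSMUSG00000058672 fell 13.1-fold, from 225.2 RPKM ± 16.4 to 17.1 RPKM ± 2.28 (SD, n = 2 each), with a limma adjusted p of 0.00093. The genes called were mostly better covered than the rest, with a median of 63.0 RPKM against 8.63 RPKM over all tested genes. Recovery of changes was not compared between levels of RPKM. All 79 had non-overlapping libraries, as had 54.4% of tested genes where chance gives 33.3%. The shared spread includes the ZT2 libraries, and a fit on the ZT0 and ZT12 libraries alone called 295 genes, 116 higher and 179 lower, with all 79 among them. Without ZT0 replicate 1 the count was 5, without ZT0 replicate 2 it was 3, and without either ZT12 library it was 5.

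**Figure D2:**
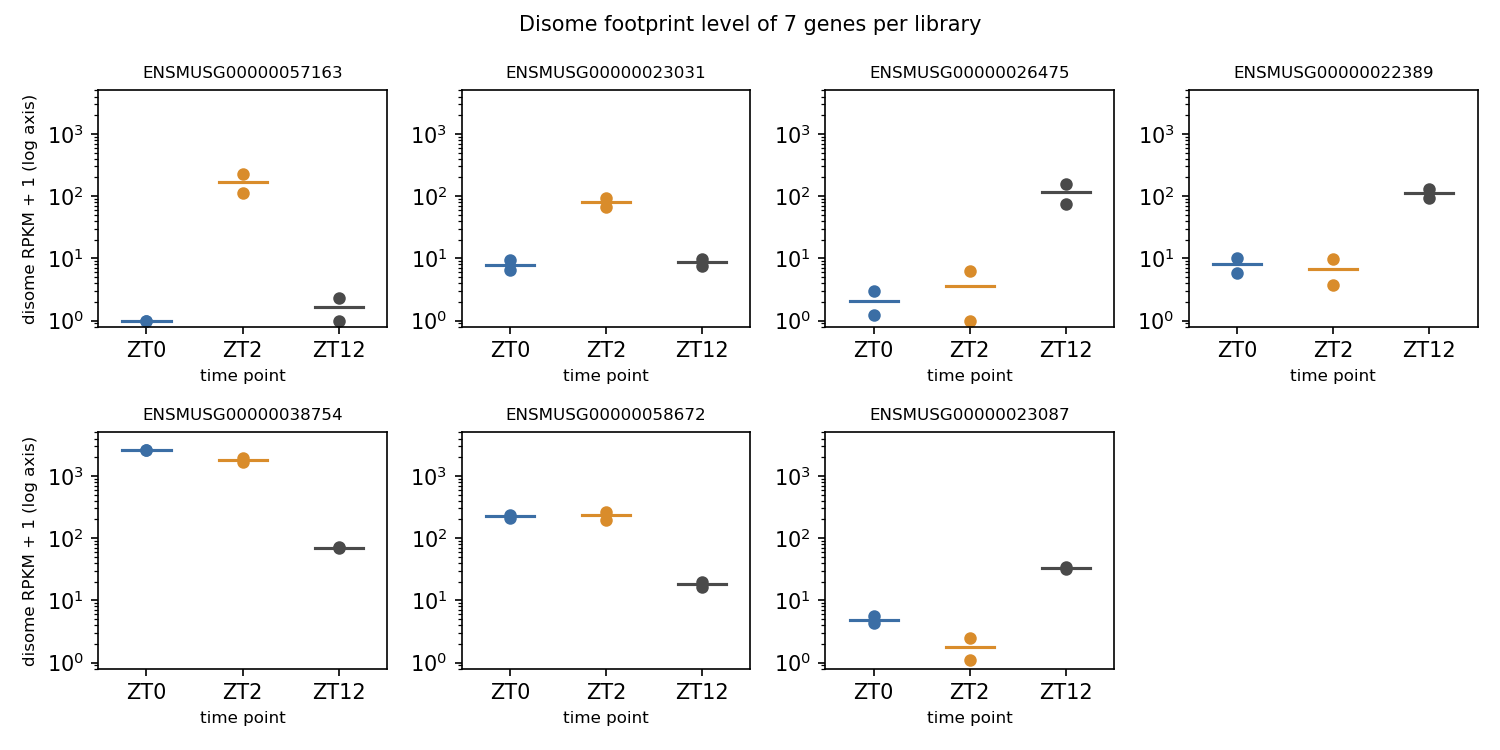
Disome RPKM + 1 on a log axis (vertical) at the 3 time points (horizontal) for the 7 genes printed in the text, with 1 point per library and a bar at the mean of the 2 libraries. ENSMUSG00000038754 falls from 2627 RPKM at ZT0 to 69.4 RPKM at ZT12, and ENSMUSG00000057163 is above 100 RPKM only in the libraries of ZT2.

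The third comparison covered the 10 h from ZT2 to ZT12. Disome levels of 172 genes differed, with 89 higher and 83 lower at ZT12, and 162 of them changed by more than 2-fold. In simulated data this test called 0 of 50 genes changed 1.5-fold and 8 of 50 changed 2-fold. The median log2 change was 1.80 among the genes that rose and -1.51 among those that fell. ENSMUSG00000026475 had the largest rise, from 2.58 RPKM ± 3.65 (SD, n = 2) at ZT2, where its reads were 0 and 24, with a log2 change of 5.45 ± 0.85 (SE) and a limma adjusted p of 0.030, a call lost in 8 alternatives at a limma adjusted p of up to 0.239. Its log2 change was 3.98 with a pseudocount of 5 and 7.21 with 0.1. ENSMUSG00000023087 rose from 0.806 RPKM ± 0.997 to 31.9 RPKM ± 1.94 (SD, n = 2 each), with a log2 change of 4.30 ± 0.41 (SE) and a limma adjusted p of 0.0067. The size depended on the pseudocount, with a log2 change of 2.68 at 5 and 5.81 at 0.1, and it was 6.21 with voom. Its ZT2 level rested on 12 and 1 reads, and the call was lost without either ZT12 library, at a limma adjusted p of up to 0.111. The largest falls were in ENSMUSG00000057163, with a log2 change of -6.72 ± 0.49 (SE) that ran from -4.87 at a pseudocount of 5 to -8.73 at 0.1 and -9.24 with voom, and ENSMUSG00000038754, which fell 26.1-fold with a limma adjusted p of 5.74e-05. Scaling every library to the same total turned the split into 132 higher and 61 lower. The shared spread includes the ZT0 libraries, with a replicate SD of 0.25 against 0.53 at ZT2 and 0.35 at ZT12. The p-values of this comparison may therefore be too small. On the ZT2 and ZT12 libraries alone the count fell to 39 genes, 20 higher and 19 lower, and with array weights it was 57. Leaving out ZT2 replicate 1 gave 609 genes and leaving out ZT2 replicate 2 gave 392. Without ZT0 replicate 1 the count was 39, without ZT0 replicate 2 it was 38, without ZT12 replicate 1 it was 46, and without ZT12 replicate 2 it was 5.

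**Figure D3:**
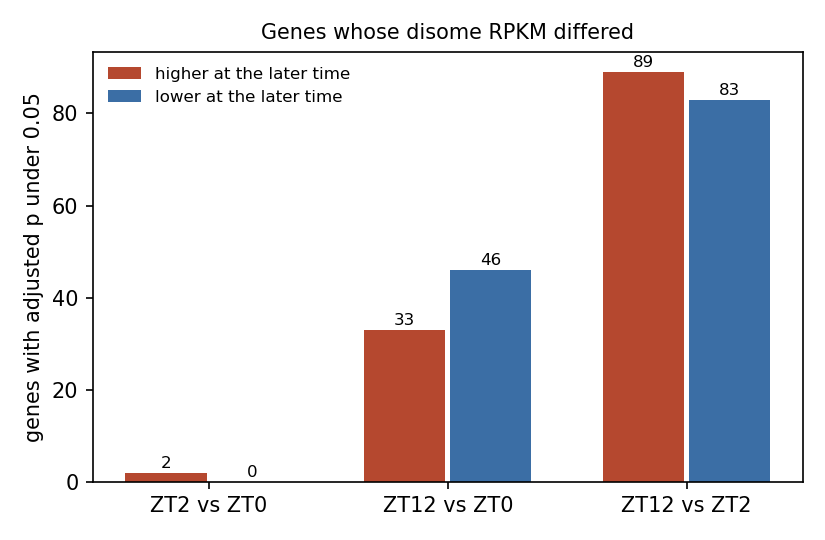
Number of genes with a limma adjusted p under 0.05 (vertical axis) that were higher or lower at the later time point in each of the 3 comparisons (horizontal axis). The bars show 2 and 0 genes for ZT2 vs ZT0, 33 and 46 for ZT12 vs ZT0, and 89 and 83 for ZT12 vs ZT2.

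Over the 3 time points together, the moderated F test in limma called 105 genes, and 1555 had an unadjusted p under 0.05. The mean level was highest at ZT12 in 44 of the 105, at ZT0 in 33 and at ZT2 in 28. It was lowest at ZT12 in 53, at ZT2 in 33 and at ZT0 in 19. The commonest courses were highest at ZT0 and lowest at ZT12 with 28 genes, highest at ZT12 and lowest at ZT2 with 28 genes, and highest at ZT2 and lowest at ZT12 with 25 genes. These courses rank the mean levels without a test of their order. Limma called 2 genes for ZT2 against ZT0, so for most of the 105 the order of ZT0 and ZT2 was not resolved. Of the genes called against ZT0 and against ZT2, 23 were higher at ZT12 in both and 41 were lower in both, and none went opposite ways (0 genes). A gene going opposite ways would need a ZT2 against ZT0 change as large as both changes together. With only 2 calls there, this absence was close to fixed beforehand and says nothing separate about the overlap. Independent lists of these sizes would share 0.352 and 0.457 genes. In 50 simulations of unchanged genes, lists of these lengths taken by the smallest p shared 8.22 genes on average and at most 13 for higher, and 10.3 on average and at most 16 for lower. Both comparisons use the same ZT12 libraries, which were not split because each part would keep 1 library, so part of the overlap may come from the shared libraries. Without ZT12 replicate 2 the F test called 5 genes, without ZT12 replicate 1 it called 13, without ZT0 replicate 2 it called 20 and without ZT0 replicate 1 it called 25. Without ZT2 replicate 1 it called 630 and without ZT2 replicate 2 it called 381.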

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

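Recovered reads ranged from 6346387 to 12322651 per library. In simulated data for the ZT2 against ZT0 test, 0, 12, 38 and 45 of 50 genes changed 1.5-fold, 2-fold, 4-fold and 8-fold were recovered among 8355 genes, with 6 false calls (0 for ZT12 against ZT0 and 10 for ZT12 against ZT2); depth and the number of libraries were not varied. Array weights, voom and the removal of genes at 0 were chosen after seeing the data. For ZT2 against ZT0, ZT12 against ZT0, ZT12 against ZT2 and the F test in turn, the counts of 2, 79, 172 and 105 became 1, 32, 80 and 34 without the variance trend and 8, 179, 423 and 305 at an adjusted p of 0.1. With voom on the recovered reads they were 9, 283, 356 and 350, and with array weights the last 3 were 414, 57 and 211. The cause of these shifts was not tested beyond what follows. Array weights were 2.09 for the ZT0 libraries, 0.473 for the ZT2 libraries and 1.01 for the ZT12 libraries. Fits on only the 4 libraries compared gave 1, 295 and 39 genes. A pseudocount of 0.1 gave 6 genes for ZT2 against ZT0, the removal of genes listed at 0 in any library gave 1, and a filter at 5 RPKM gave 124 genes for ZT12 against ZT0. Leaving out each library in turn gave 0 to 256, 3 to 300, 5 to 609 and 5 to 630 genes. A lone library is there assumed to vary like the other groups; the low counts came from removing a ZT0 or ZT12 library, which leaves the ZT2 spread with more weight, and the high ones from removing a ZT2 library. Scaling to the same total moved the median log2 change of all genes to -0.11 for ZT2 against ZT0 and 0.17 for ZT12 against ZT2. The 15 most abundant genes held 39.4% of summed RPKM, and 38.8% to 40.1% when each library was left out. Deviations of same-numbered libraries correlated at -0.076, -0.019 and 0.018, so the numbers did not pair the libraries. With the replicate number as a block the counts were 2, 51, 113 and 76. A pseudocount of 5, no filter, the other scalings and the robust prior kept the counts of 2, 79, 172 and 105 within 1.5 times. Of 206 values for the named genes, 174 stayed past the threshold, 32 lost it and 0 changed direction; the calls lost are given with each gene, and ENSMUSG00000026475 lost its call most often, in 7 settings against ZT0 and 8 against ZT2. No gene was missing from any table, so the alternative for absent genes changed nothing, and the gene list alternatives were not run because no list could be matched.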

Other observations

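The tests on coding length and on the clumping of reads, and that of the variance between time points, were planned before their results were seen; those on read sampling, on lower levels at ZT2 and on the spread of the ZT2 libraries were chosen afterwards. The requirement that the clump estimate also hold in other libraries was added after its result was seen. Among the listed genes, disome RPKM was higher on short coding sequences. The gene filter behind the list is not given. A filter on reads would keep short genes only at a high RPKM, so part of this relation may come from the list itself. The 2090 tested genes with 54 to 819 coding nucleotides had a median of 21.3 RPKM ± 1.31 (SD, n = 6), and the 2087 genes with 2097 to 26397 nucleotides had 4.04 RPKM ± 0.257 (SD, n = 6). The short genes held 31.7% ± 1.69 (SD, n = 6) of recovered reads and the long ones 15.0% ± 0.429 (SD, n = 6). Across genes, which are not independent replicates, Spearman's rho between RPKM and coding length was between -0.475 and -0.401 in the 6 libraries. From the shortest to the longest of 4 nearly equal classes of coding length, limma's F test called 41, 25, 32 and 7 genes, without a test between classes. Recovery of changes was not compared between levels of RPKM or coding length, so these counts do not show that fewer of the long genes changed. Transcript amounts were not analysed here, so disome density could not be set against them.

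Some genes stood apart at a single time point, with both libraries at least 4 times every other library and at least 20 reads after scaling to ZT0 replicate 2. There were 2 such genes high at ZT2, 7 high at ZT12 and 0 high at ZT0. In the other direction, 17 genes were low at ZT12 alone, 3 at ZT2 and 0 at ZT0. Which cells or tissue the reads of these genes came from was not tested.

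The first pattern is the 250 genes listed at 0 in ZT2 replicate 2, whose median expected number of reads from the other libraries was 14.9. Read sampling at this depth is argued against, since 1000 Poisson draws gave at most 3 genes at 0. The other libraries also exceeded their highest draws, with 97 genes against 6 in ZT2 replicate 1 and 4 against 3 in ZT0 replicate 2. Poisson sampling thus fell short in every library, not only for the 250 genes. Lower levels at the ZT2 time point are argued against as well: where ZT0 had reads, these genes lay in ZT2 replicate 1 at a median log2 difference of 0.044 from ZT0 (quartiles -0.53 and 0.52). Reads in clumps from few distinct fragments stay open: a clump size of 10.7 reads estimated from better covered genes predicted 471.3 genes at 0 among those under 30 expected reads, 1.99 times the 237 observed there, just inside the limit of 2 set beforehand for this explanation, but the same kind of estimate overshot 3.99 to 45.6 times in the other 5 libraries. ZT2 replicate 2 also had 98 genes with 1 to 3 reads, 21 of them with 1 read, which clumps of a fixed 10.7 reads would not give. In simulated reads, the estimate predicted 54.4 genes at 0 against 30 for clumps of 3 reads. For clumps of 6 reads it predicted 224.6 against 209. The 14 genes at 0 in both ZT2 libraries compare with 2.71 for independent lists of those lengths, which ignores that low genes are likelier to be at 0.

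The second pattern is the 2 genes called for ZT2 against ZT0 beside 79 for ZT12 against ZT0. The spread between the ZT2 libraries as the whole cause is argued against for these counts from the shared fit. There a gene has the same SE in each comparison (median 0.293), so this spread widened both equally. Simulated changes of 2-fold, 4-fold and 8-fold were recovered for 12, 38 and 45 of 50 genes for ZT2 against ZT0. For ZT12 against ZT0 they were recovered for 5, 34 and 47 of 50. For fits on only the 4 libraries compared, the question stays open. ZT12 against ZT2 then called 39 genes, above a limit of 10 set after this result was seen. ZT2 against ZT0 called 1 although its replicate variance was lower (0.170 against 0.202), while ZT12 against ZT0 called 295. Fits without 1 of the ZT2 libraries cannot decide this, since the lone ZT2 library is then assumed to vary like the other groups. Smaller changes between ZT2 and ZT0 are consistent with the variance of log2 changes beyond the replicate spread, 0.0998 for ZT2 against ZT0 and 0.196 for ZT12 against ZT0, a ratio of 0.509 (95% bootstrap interval over genes 0.415 to 0.616). That interval treats genes as independent and may be too narrow, and the ratio rests on the ZT2 spread as estimated from 2 libraries.

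The third pattern is the 79 genes called for ZT12 against ZT0. Across genes the log2 change rose with coding length, with a Spearman's rho of 0.167, and the genes that fell had a median of 924 coding nucleotides against 1296 for those that rose. A coding length bias between libraries is argued against as the source of the calls, since 77 of the 79 remained after each library's trend on length was removed, which brought rho to -0.0196. Whether the trend itself reflects time of day or library preparation could not be told from these values.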
